A study of Mus musculus with 411 samples.

How the data were processed

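Single retinal ganglion cells (RGCs) of mice 6 to 8 weeks old were sequenced with Smart-seq2, a plate method that makes 1 full-length library per well and carries no molecular identifiers. Per the labels' protocols, the optic nerve was crushed, a fluorescent dextran called micro-Ruby was placed about 1.5 mm beyond the crush on day 20, and cells were sorted 24 h later, on day 21. A cell with the dextran (MR+) had an axon past the crush and is called regenerating. A cell without it (MR−) is called surviving. The sort took YFP-positive cells with high CD90 and left out debris, doublets and dead cells, per the labels' protocols. The 411 deposited samples are 411 cells in 4 groups. The labels name no animal or retina.

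Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.39, aligned to GRCm38 with HISAT2 and assigned to genes with featureCounts. The annotation and the counting settings are not given in the sources used here. The deposited table is named as counts, but the deposited values are a signal of reads per kilobase of each gene's full span, introns included, with no scaling for library size. This was found from the values: multiplied by the span in kilobases, all of them (100%) came within 0.001 of a whole read. The span was taken from the GENCODE M21 annotation (GRCm38) for 20775 of the 27498 genes with a value, which hold 70.9% of the reads, and solved from the values themselves for 6723. Whole reads follow by construction for the 6723 solved spans, so only the 20775 annotated ones bear on this reading. The analysis had been designed for counts, and whole reads recovered in this way were used throughout. Reads on 1132 unnamed entries (0.110% of all reads) were left out. Coordinates are printed only where the annotation gave the span.

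The following choices were made before the data were examined: the cell filter, the gene lists, the cell type markers, the comparisons, the rule for naming genes and most of the alternatives. A cell was kept with at least 100000 reads, at least 2000 genes with a read, and at least 3 of 8 pan-RGC markers (Rbpms, Slc17a6, Nefl, Nefm, Sncg, Thy1, Pou4f1, Pou4f2) at 10 CPM, which are reads scaled to a total of 1000000, or more. Depth and gene number removed 19 cells, the marker rule removed 51, and 341 were kept: 117 of 120 Pten cells, 25 of 46 Pten CNTF cells, 166 of 179 regenerating Pten Socs3 CNTF cells and 33 of 66 surviving cells. A clustering used the 392 cells that passed the depth filter. Reads per cell ran from 290911 to 2902831 with a median of 1305541.

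For each group the reads of the kept cells were summed and divided by the group's total to give CPM, with exact Poisson 95% intervals. A gene's log2 ratio between groups used a pseudocount of 1 CPM. Folds are ratios of CPM without a pseudocount. The share of cells with a gene was counted at 1 read or more after each cell was thinned to 100000 reads, with exact Clopper-Pearson 95% intervals. Reads that share a PCR origin are not independent molecules, so intervals and floors cover counting error only. Where a group had 0 reads of a gene, the fold was taken against a floor of 3 reads over the group. It is not a bound for the sampling of cells, since another cell with the gene could lower it. Genes at 5 CPM or more in any group counted as measured (12173 genes).

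Cells of an unnamed number of animals are not replicates, so each group was treated as 1 sample. No test was run, and no p-value or count of changed genes is given. Gene lists were summarised by the median log2 ratio of their measured members, with its percentile among 10000 random lists of equal size matched on mean expression. Titles of the samples fall into 8 series by a letter in the title or its absence. What the letters stand for is not stated, and the series were used only as a technical split: regenerating Pten Socs3 CNTF cells in D, F, R and an unlettered series, surviving cells in B, Pten cells in C and an unlettered series, and Pten CNTF cells in an unlettered series alone.

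The 13 gene lists are regeneration-associated, JAK-STAT and cytokine response, interferon response and antigen presentation, RGC identity, ion channel and synaptic, growth cone and cytoskeleton, integrated stress and cell death, ribosomal protein and elongation factor, cholesterol synthesis, oxidative phosphorylation, glycolysis and hypoxia, RGC survival and regeneration candidates, and axon guidance and growth inhibition. The candidate list was recalled from published RGC injury work, part of which may rest on these cells, so it is not independent evidence. The 18 marker lists cover pan-RGC, rod, cone, bipolar, amacrine, Muller glia, astrocyte, microglia or macrophage, T cell, endothelial and pericyte markers, and the alpha, Eomes or photosensitive, Foxp2, Tbr1, Neurod2, direction-selective and Tusc5 RGC subclasses. Tusc5 is listed in the table as Trarg1.

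Genes were named in each comparison if they had at least 20 CPM and detection in 20% of cells in the higher group, a log2 ratio of at least 1 from summed reads and from per-cell means, shares that differ by 15 percentage points, and every title series of 10 or more kept cells on the same side of every such series of the other group. Predicted genes, mitochondrial genes and pseudogenes, by symbol or by the annotated gene type, were left out. The 10 highest and 10 lowest by mean per-cell log2 difference were taken. Also named were Pten, Socs3 and Cntf, up to 2 members at each end of each list, and the cell type markers. Because the rule selects on the title series, the separation of series is not evidence for these genes.

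On simulated reads for the regenerating over surviving comparison with 44946 genes, of which 200 were altered, the steps gave a median log2 ratio of 1.06 for 67 genes made 2-fold different, 2.14 for 67 made 4-fold different and 2.97 for 66 made 8-fold different. The direction was right for 100% at each size. The naming rule picked 10.4%, 50.7% and 60.6% of them, and 30 of 7160 unaltered genes (0.419%). Of 100 unaltered lists of 17 genes, 9 fell outside the middle 95% of random lists. The simulation drew each gene separately from 1 mean over both groups, with no effect of title series or RGC subclass. These rates therefore do not cover such effects.

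Alternatives covered equal weights for cells, no cell filter, no pan-RGC rule, a stricter filter of 500000 reads and 4000 genes, pseudocounts of 0.1 and 5 CPM, no minimum or 20 CPM for list members, scaling by the trimmed mean of M values and by the median of ratios, lettered or unlettered series alone, leaving out each title series, no thinning, and 3 reads for detection. Under the 3 scalings the median of all measured genes stayed within 0.1 of 0 on the log2 scale in every comparison. The clustering (Leiden, 2000 variable genes, 20 components, 15 neighbours) served to describe the makeup of the cells. The rule for weighing explanations in the closing section was revised after its results were seen: it first asked only whether a median kept at least 50% of its value, and now asks that it do so by more than the standard deviation between title series. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2 and matplotlib 3.10.9 were used.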

Results

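The data are gene expression profiles of 411 single mouse RGCs taken 21 days after optic nerve crush. Regenerating cells, which had taken up a dextran placed in the nerve beyond the crush, came from 3 treatments. In the Pten group a virus carrying Cre deleted Pten (120 cells). In the Pten CNTF group Cre was joined by a virus for CNTF, a cytokine that acts on RGC survival and growth (46 cells). In the Pten Socs3 CNTF group both Pten and Socs3, a brake on cytokine signalling, were floxed and CNTF was added (the remaining regenerating cells). Surviving cells, without the dextran, came from the Pten Socs3 CNTF treatment only (66 cells). The Pten CNTF group follows the virus label, while its description label names only the Pten deletion.

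The cell filter kept 25 of the Pten CNTF and 33 of the surviving cells, most Pten cells and 92.7% of the regenerating Pten Socs3 CNTF cells. In the order Pten, Pten CNTF, regenerating Pten Socs3 CNTF and surviving, their median depths were 1464140, 1485470, 1211890 and 1135450 reads per cell, and their median numbers of genes were 6608, 5849, 9060 and 8583. No animal is named, so there are no replicates and each difference has no replicate check. All values describe these cells alone. The unlettered Pten Socs3 CNTF series kept 11 of 22 cells, with medians of 771986 reads and 3289 genes. Series D, F and R of that group had medians of 8759 to 9380 genes. Y-linked transcripts at 10 CPM or more were in 27.3% of those 11 cells, against 90.2% to 95% in D, F and R. Low detection and title series cannot be told apart in values for those 11 cells. A list median given for 1 title series weights its cells equally, except where the whole comparison was kept within the lettered or the unlettered series. Random lists were drawn for all kept cells pooled, with summed reads. Their limits are therefore not the range expected within 1 title series or another subset of cells.

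The targeted genes were examined first. Pten had 34.04 CPM in Pten cells (95% interval 33.2 to 34.9), 30.5 in Pten CNTF cells (28.7 to 32.3), 37.8 in regenerating Pten Socs3 CNTF cells (36.98 to 38.6) and 45.3 in surviving cells (43.1 to 47.5). These reads cover the whole gene (GRCm38 chromosome 19, 32757497 to 32826160, plus strand), so the floxed part is not resolved and they do not check the deletion. Socs3 (chromosome 11, 117966079 to 117970047, minus strand) had 11.9 CPM (11.4 to 12.5) in Pten cells. It had 86.5 (83.5 to 89.6) in Pten CNTF cells, 34.6 (33.8 to 35.4) in regenerating Pten Socs3 CNTF cells and 25.3 (23.7 to 26.97) in surviving cells. Socs3 was thus 7.24-fold higher with Pten CNTF than with Pten, and 2.4995-fold lower with Pten Socs3 CNTF than with Pten CNTF in summed reads. The mean per cell was lower too (33.1 CPM against 85.5), but the median per cell was not (18.8 against 4.002), nor was the share of cells with Socs3 (64.5%, interval 56.7% to 71.7%, against 48%, 27.8% to 68.7%). Its reads also cover the whole gene. In the 11 unlettered Pten Socs3 CNTF cells the mean per cell was 0.583 CPM for Pten and 5.69 for Socs3, against 26.8 to 53.2 and 30.9 to 37.2 in the lettered series of that group. Cntf is listed at 0 in every group, as is the abundant gene B2m, so a 0 here need not mean that a transcript was absent.

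Regenerating and surviving cells of the same Pten Socs3 CNTF treatment address what sets apart an RGC that regrew its axon. Regenerating cells had more of the injury and regeneration genes, led by Sprr1a and Gal. When all cells were pooled they also had more interferon-response transcripts and more growth cone and cytoskeleton transcripts, and more of them carried microglia or macrophage markers (36.7% against 9.09%). Ion channel, synaptic and axon guidance genes were lower in regenerating cells when all cells were pooled, but differed less in series F and R. The acetylcholine receptor genes Chrna6 and Chrnb3 were higher in surviving cells.

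Sprr1a, a small proline-rich protein induced in injured neurons (chromosome 3, 92483952 to 92485895), was the gene of the regeneration-associated list furthest toward regenerating cells: 2479 CPM against 338.8, a 7.32-fold difference. It was found in 90.96% of regenerating and 60.6% of surviving cells. The neuropeptide Gal had 3703 CPM against 508 (log2 ratio 2.86). Of 17 measured genes of that list 15 were higher, among them Cd44 (2.09), Klf6 (1.83), Hspb1 (1.53), Gap43 (1.51) and Atf3 (1.14), while Sox11 (−1.61) and Basp1 (−0.02) were lower. The list's median was 1.19, at percentile 100 of random lists, whose middle 95% ran from −0.29 to 0.28. With cells weighted equally the median was 1.29 in title series D, 0.67 in F and 1.19 in R, and −0.28 in the 11 unlettered cells.

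Further genes named in this comparison were Cfap77 (25.5 CPM against 1.18, log2 ratio 3.61), the surface protein Ly6a (2.95), the cytokine Csf1 (2.27), the RNA-binding regulator Arid5a (1.56), the neuronal serine protease Prss12 (1.24) and the proteoglycan Sdc1 (1.03). Ly6a has close paralogs that share reads, which leaves its own level uncertain. Rsad2, an interferon-induced gene, was found in 65.1% of regenerating and 30.3% of surviving cells (log2 ratio 2.49). The interferon list was higher in 16 of 20 genes (median 0.72, percentile 100), with Psmb8 at 1.78. By series its median was 0.26 in D, 0.59 in F, 0.67 in R and 0.58 in the unlettered cells. The value in D was at the upper limit of the pooled random lists (0.25).

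Growth cone and cytoskeleton genes were higher in 22 of 23 (median 0.51), with Tagln2 at 2.49 and Tubb6 at 1.46. By series their median was 0.65 in D and 0.43 in R, but 0.21 in F and 0.17 in the unlettered cells. The upper limit of the pooled random lists was 0.21. Stress and cell death genes were higher in 11 of 16 (0.47), with Cdkn1a at 2.16 and Ddit3 at 1.36, while Bbc3 was lower (−2.29); with cells weighted equally their median was 0.80 in series D, 0.29 in F, 0.14 in R and −0.17 in the unlettered cells. JAK-STAT genes were higher in 12 of 15 (0.35), with Socs1 at 1.68 and Il6st at 1.50 and with Bcl3 lower (−1.39). That median lay barely above the random lists (percentile 97.9, limit 0.33), and was 0.26 in series D and −0.25 in the unlettered cells. Ribosomal genes were higher in 14 of 17 (0.40), but the median was −0.085 without title series D. In the candidate list 15 of 22 genes were higher (0.58), with Spp1 at 2.92 and Tac1 lower (−1.06), but by series the median was 0.73 in D, 0.10 in F, 0.49 in R and −0.80 in the unlettered cells.

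Surviving cells had more Dkk3, a secreted Wnt regulator (530.4 CPM against 134.9, log2 ratio −1.97), and more of the acetylcholine receptor subunits Chrna6 (224 against 61.4) and Chrnb3 (289 against 125.9). They also had more of the glutamate receptor Gria3 (−2.00), the peptide receptor Vipr2 (−1.93), Btbd11 (−1.78), the transcription factors Pou6f2 (−1.39) and Ebf4 (−1.23), and AC149090.1 on an unplaced scaffold (−2.56). RGC subclass makeup was not held constant in these values, so it is not separate from survival here. The subclass marker Trarg1 was itself higher in surviving cells (−1.57). Trarg1 and Vipr2 were both among the leading genes of 1 cluster in the clustering. That cluster held 22 kept surviving cells and 28 of the far more numerous kept regenerating cells. Snca met the naming rule at −1.005, but was 0.013 without the pan-RGC rule. Ion channel and synaptic genes were lower in regenerating cells in 18 of 23 (median −0.30, percentile 0.467), with Scn4b at −2.17 and Cplx2 at −1.52 and with Gria1 higher (0.69). Axon guidance genes were lower in 16 of 21 (−0.54, percentile 0), with Rtn4r at −1.47 and Sema3a at −1.27 and with Plxna4 higher (1.02). With cells weighted equally, ion channel medians were −0.46 in series D, −0.13 in F, −0.19 in R and −2.62 in the 11 unlettered cells. Axon guidance medians were −0.99, −0.18, −0.12 and −2.88. For both lists F and R lay inside the middle 95% of the pooled random lists. Glycolysis genes were lower in 11 of 12 (−0.26, percentile 3.74), inside the middle 95% of random lists. RGC identity (−0.01) and cholesterol synthesis (−0.10) had medians near 0 when all cells were pooled, but −1.52 and −0.67 in the unlettered cells. The oxidative phosphorylation median of 0.01 pooled unlike series, with −0.54 in F, −0.30 in R, 0.25 in D and 0.72 in the unlettered cells. All surviving cells came from 1 title series, B, so that series and survival without regrowth cannot be told apart.

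**Figure D1:**
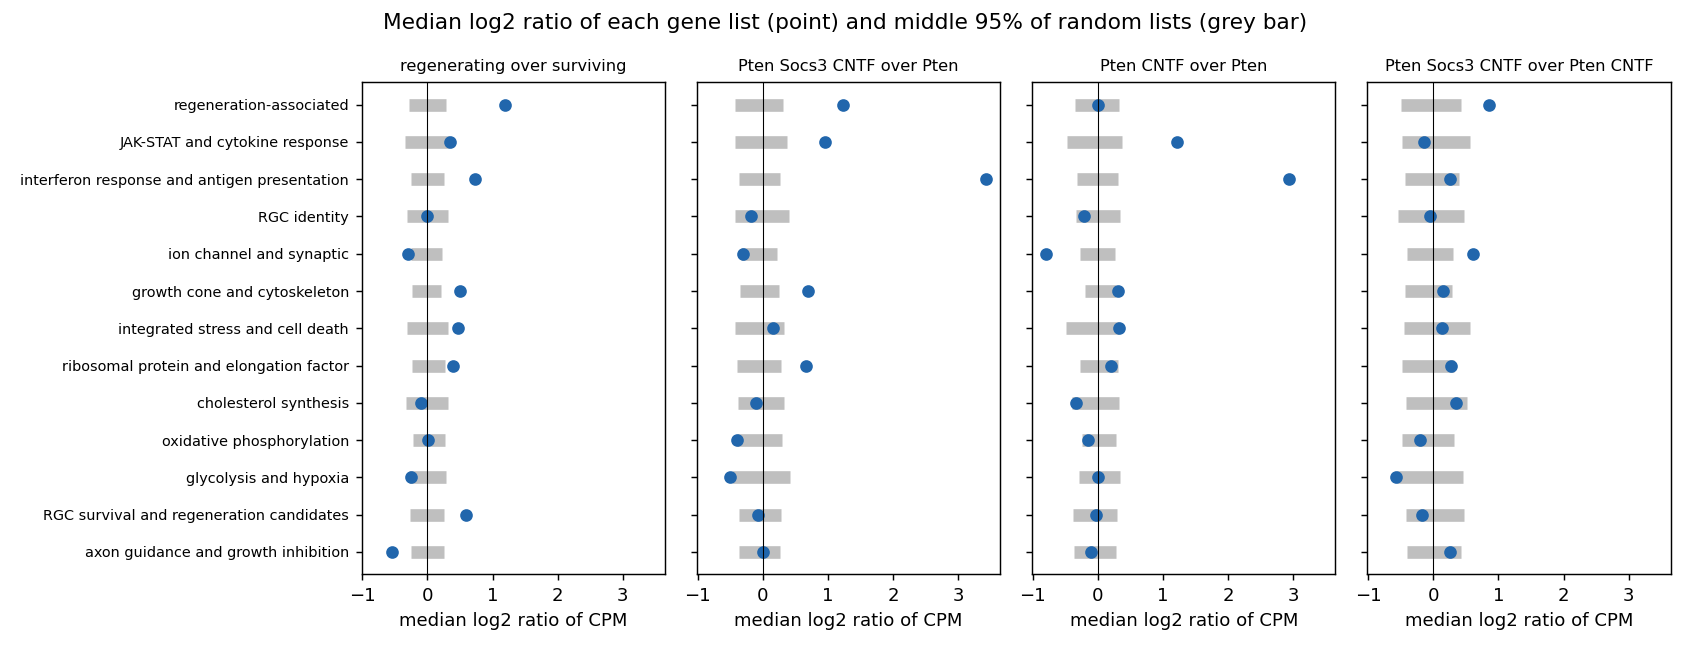
Median log2 ratio of each gene list in the 4 comparisons, with the middle 95% of random lists of matched expression. Interferon genes had the highest median in both comparisons with Pten cells (3.43 and 2.94), and regeneration-associated genes in the comparison of regenerating with surviving cells (1.19).

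**Figure D2:**
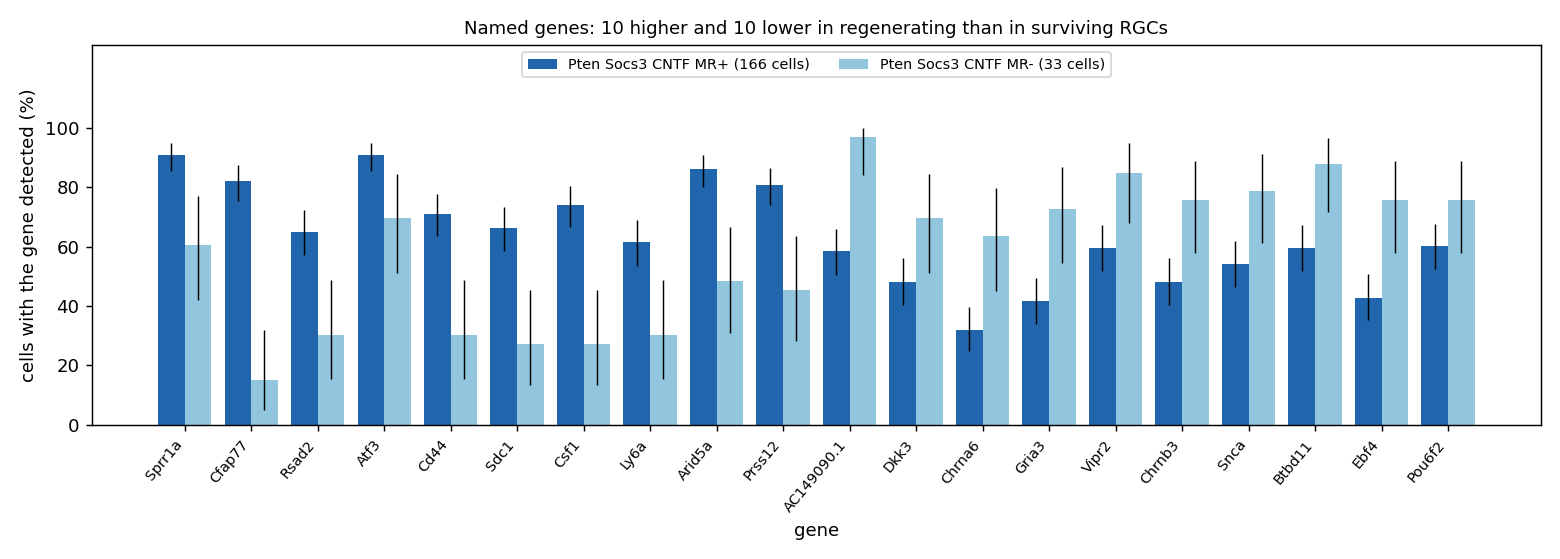
Percent of regenerating and surviving Pten Socs3 CNTF cells with each named gene after thinning to 100000 reads, with exact 95% intervals. Sprr1a was found in 90.96% of regenerating and 60.6% of surviving cells.

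The Pten Socs3 CNTF treatment over the Pten treatment, both in regenerating cells, addresses what the added cytokine and the Socs3 deletion bring to a cell that regrows its axon. The largest difference was in interferon-response and antigen-presentation genes, which were higher with Pten Socs3 CNTF in every measured member. Regeneration-associated, JAK-STAT and growth cone genes were higher too. So were microglia or macrophage markers (36.7% against 6.84% of cells) and Muller glia markers. Pten cells had more of the alpha RGC markers Spp1 and Kcng4.

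All 20 measured interferon genes were higher, with a median log2 ratio of 3.43 (percentile 100). Ifit1 had 2131 CPM against 202.5, a 10.5-fold difference, and Rsad2 was 77.2-fold higher (6.07). Isg15 (5.02), Irf7 (3.59) and Oasl2 (2.62) stood on the same side, as did Ifi44 (5.18) and the GTPase Iigp1 (3.90), named outside the list. Class I genes H2-Q4 (5.31), H2-Q10 (5.30) and H2-Q2 (3.61) were also higher. Ly6a was 117.9-fold higher (6.61). Near-identical copies in the H2-Q, Ly6, Serpina3 and Ifit families share reads, and the strain labels differ between these treatments, so single members are uncertain.

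JAK-STAT genes were higher in 13 of 15 (median 0.95), with Serpina3n at 1289 CPM against 96.7 (13.3-fold) and Socs1 at 4.26. That median was 0.25 within the unlettered series alone, 0.54 without cells that have a microglia or macrophage marker and 0.51 without cells that have a rod marker. Regeneration-associated genes were higher in 14 of 17 (1.23), with Gal at 2.57, Plaur at 2.02 and Sox11 at −1.25, and with a median of 0.08 in the 11 unlettered cells. Growth cone genes were higher in 22 of 23 (0.69), with Tubb2b at 2.84. Ribosomal genes were higher in 14 of 17 (0.66), but with cells weighted equally the median was 1.23 in series D, −0.27 in F, 0.25 in R and 0.01 in the unlettered cells, and −0.02 against Pten series C. The transcription factor Wt1 had 52.5 CPM against 0.149 (5.54), and the neuropeptide Penk had a log2 ratio of 5.54.

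Spp1, the secreted protein osteopontin, was 36.4-fold lower with Pten Socs3 CNTF (17.2 CPM against 624). The potassium channel subunit Kcng4 had 9.78 CPM against 101.6 (−3.25). Other genes lower with Pten Socs3 CNTF were the glycolytic gene Eno1b (6.04 CPM against 158.1), the actin regulator Coro6 (−3.01), the serotonin receptor Htr1d (−2.86), Sgpp2 (−2.72), Chrnb3 (−2.57), Chrna6 (−2.32), Kcnab3 (−1.97) and Dkk3 (−1.95). Glycolysis genes were lower in 10 of 12 (median −0.50, percentile 1.58), with Pgam1 at −1.10 and Pkm at −0.93. Their median was −0.59 against the unlettered Pten series but −0.25 against Pten series C. The lower limit of the pooled random lists was −0.47. Oxidative phosphorylation genes were lower in 14 of 16 (−0.40), inside the middle 95% of random lists. With cells weighted equally their median was −0.89 in series F and −0.71 in R, but −0.01 in D and 0.27 in the unlettered cells. Ion channel and synaptic genes were lower in 14 of 23 (−0.30, percentile 4.25), inside the middle 95% of random lists, with Scn4b at −2.27 and Gria1 higher (2.27). Their median was −0.43 in series D, −0.10 in F, −0.12 in R and −2.30 in the unlettered cells. Stress (0.16), RGC identity (−0.18), cholesterol synthesis (−0.11) and candidate (−0.08) medians lay inside the random lists, though in the unlettered cells they were −0.51, −1.51, −0.26 and −0.97, and that of stress genes 0.40 in D. So did that of axon guidance genes (0.01), which by series was 0.43 in F, 0.36 in R, −0.17 in D and −2.44 in the unlettered cells. The treatments used different floxed lines, and Y-linked transcripts at 10 CPM or more were in 0% of Pten cells (interval up to 3.10%) against 87.95% of regenerating Pten Socs3 CNTF cells, so line, sex and treatment go together.

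**Figure D3:**
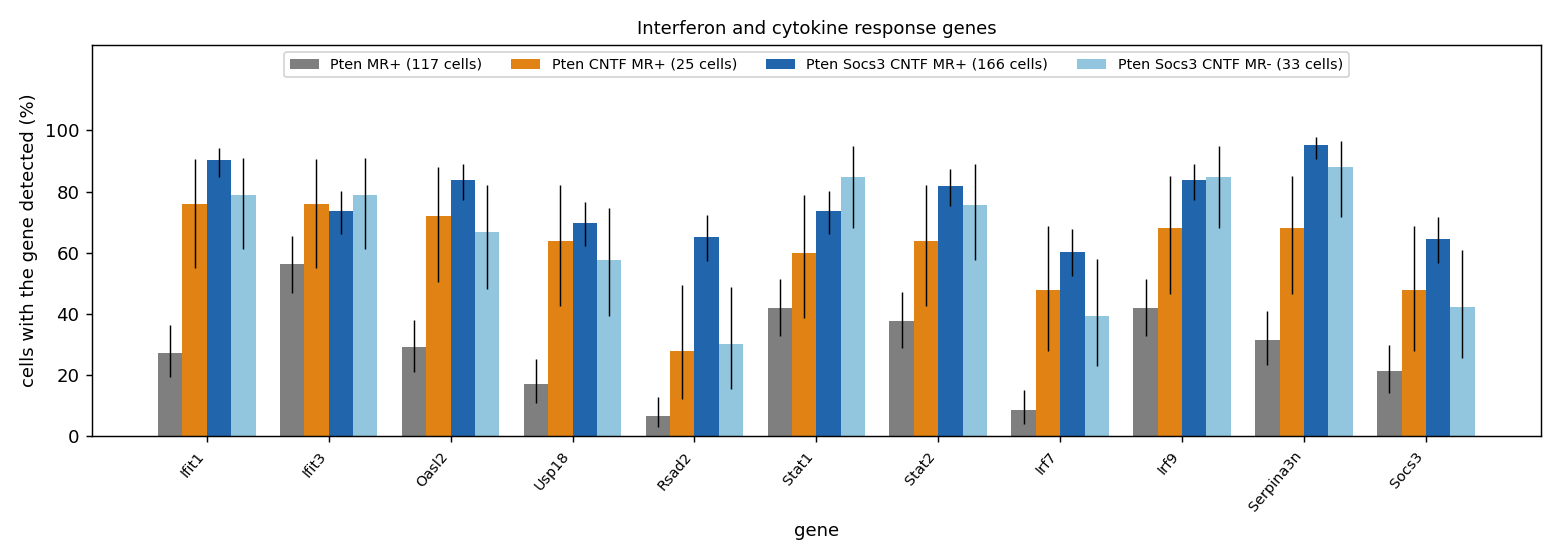
Percent of cells of the 4 groups with each interferon or cytokine response gene after thinning to 100000 reads, with exact 95% intervals. Rsad2 was found in 65.1% of regenerating and 30.3% of surviving Pten Socs3 CNTF cells.

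Adding CNTF to the Pten deletion, both in regenerating cells, addresses the cytokine without the Socs3 deletion. Interferon and JAK-STAT genes were higher with Pten CNTF in every measured member. Regeneration-associated genes had a median near 0. Ion channel and synaptic genes and alpha RGC markers were lower, and rod photoreceptor transcripts were higher.

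Interferon genes had a median log2 ratio of 2.94 with 20 of 20 higher. Ifit1 had 2630 CPM against 202.5 (3.69), and Gbp2 (5.88), Rsad2 (5.35), Usp18 (3.31), Gbp3 (3.13), Oasl2 (2.99), H2-K1 (2.39) and Rtp4 (2.36) stood on the same side. H2-Q4 (3.92) and the DNA sensor gene Ifi202b (3.55) were also higher, with reads shared among near copies of both. JAK-STAT genes had a median of 1.21 with 15 of 15 higher, including Cebpd (2.57), Socs1 (2.44), Serpina3n (2.40) and Stat3 (1.21). These groups also differ in the second virus that carried CNTF.

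The regeneration-associated median was 0.01 (percentile 54.8), with 9 of 17 genes higher, Gap43 at 1.21 and Adcyap1 at −1.91. Growth cone genes were higher in 14 of 23 (0.31), with Marcksl1 at 1.65 and Dcx at −1.36, and their median was −0.00744 without the unlettered Pten series. Ion channel and synaptic genes were lower in 21 of 23 (−0.80, percentile 0). Medians of the other lists were 0.32 for stress, with Bbc3 at 0 reads, −0.34 for cholesterol synthesis, −0.21 for RGC identity, 0.19 for ribosomal genes, −0.15 for oxidative phosphorylation, −0.01 for glycolysis, −0.03 for candidates and −0.11 for axon guidance. Some turned with the Pten series. Against series C and then the unlettered series, medians were −0.17 and 0.54 for ribosomal, −0.11 and 0.29 for stress, and 0.22 and −0.04 for glycolysis genes. Those of candidate genes differed in size but not in sign (0.57 and 0.15).

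Kcng4 had 0 reads in Pten CNTF cells against 101.6 CPM in Pten cells, which is 1227-fold lower against the floor over the group. That floor covers read counting only. With 25 Pten CNTF cells kept, the interval for the share of cells with a gene at 0 reads reached 13.7%. The intermediate filament gene Prph, at 0 reads, was 345.3-fold lower against the same floor. Also lower with Pten CNTF were Ucn (−4.22), Coch (−3.63), Spp1 (−3.39), Htr1d (−3.01), the adenylyl cyclase-associated gene Cap1 (−2.54), the GABA transporter Slc6a1 (−2.50), Coro6 (−2.43), Ankrd29 (−2.13), Kcnab3 (−1.79) and Lhfp (−1.67). Rod genes were higher in 6 of 6, with Rho at 432 CPM against 24.4 and Gnat1 at 542 against 35.8. Y-linked transcripts were in 48% of Pten CNTF cells (27.8% to 68.7%), so sex and treatment are not separate here.

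Pten Socs3 CNTF over Pten CNTF addresses the loss of Socs3 when the cytokine is present in both. The groups also differ in floxed line and in Y-linked transcripts at 10 CPM or more (87.95% against 48% of cells). Line and sex are therefore not separate from the loss of Socs3. Regeneration-associated genes were higher with Pten Socs3 CNTF. Interferon and JAK-STAT medians lay inside the random lists when all cells were pooled, and differed in the unlettered Pten Socs3 CNTF cells. Microglia or macrophage markers rose as well (36.7% against 8% of cells). Amacrine markers were higher among kept cells. However, the pan-RGC rule had left out 14 Pten CNTF cells, 6 with at least 2 amacrine markers. It left out 3 regenerating Pten Socs3 CNTF cells, 1 with at least 2. The amacrine difference is therefore not separate from that rule. Rod genes were lower, and the regeneration-associated median of 0.86 was 0.38 without cells that have a rod marker. That restriction left only 7 Pten CNTF cells. Ion channel and synaptic genes were higher when all cells were pooled, but lower within the unlettered series. Several of the genes lowest with Pten Socs3 CNTF also differed between the title series of the Pten group.

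Regeneration-associated genes were higher in 15 of 17 (median 0.86, percentile 99.99), with Plaur at 0 reads in Pten CNTF cells and 114.8-fold higher against the floor. The median was 0.30 for the 11 unlettered Pten Socs3 CNTF cells with cells weighted equally. Ion channel and synaptic genes were higher in 19 of 23 (0.62), but their median was −1.26 within the unlettered series alone, the only kind of series that both groups have. JAK-STAT genes were higher in 7 of 15 (−0.14, percentile 27.1) and interferon genes in 13 of 20 (0.26, percentile 91.9). In the 11 unlettered cells, weighted equally, these medians were −0.87 and 0.66. The limits of the pooled random lists on those sides were −0.48 and 0.40, but no random lists were drawn for the 11 cells. Glycolysis genes were lower in 11 of 12 (−0.58, percentile 1.43), barely beyond the random lists, whose lower limit was −0.554. By series their median was −0.549 in D, −0.683 in F, −0.481 in R and −0.565 in the unlettered cells. Other medians lay inside the middle 95% of random lists: 0.27 for ribosomal, 0.14 for growth cone, 0.13 for stress, 0.34 for cholesterol synthesis, −0.21 for oxidative phosphorylation, −0.06 for RGC identity, −0.17 for candidate and 0.26 for axon guidance genes. All but cholesterol synthesis pooled series of opposite sign. In the order D, F, R and unlettered, the medians were 0.78, −0.52, −0.02 and −0.37 for ribosomal, 0.45, −0.26, 0.06 and 0.06 for growth cone, and 0.35, −0.15, 0.12 and −0.34 for stress genes. They were 0.22, −0.85, −0.63 and 0.27 for oxidative phosphorylation, 0.37, 0.19, 0.07 and −0.90 for RGC identity, 0.10, −0.25, −0.65 and −0.61 for candidate, and −0.26, 0.62, 0.54 and −2.41 for axon guidance genes.

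Named genes higher with Pten Socs3 CNTF were Ly6a (6.49), the Wnt receptor Lgr4 (4.97), Cfap77 (4.44), the proteoglycan Ncan (3.36), Cap1 (2.08), the palmitoyltransferase Zdhhc2 (2.03), Pcp4l1 (1.82), the lysosomal enzyme Ids (1.79) and the RNA-binding gene Pum1 (1.73). The receptor gene Gpr137 (2.83) was 0.39 against the 11 unlettered Pten Socs3 CNTF cells alone.

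Named genes lower with Pten Socs3 CNTF were Ifi202b (−6.67), Gnat1 (−4.08), Eno1b (−3.75), Habp4 (−3.25), the mitochondrial kinase gene Pink1 (−2.59), Inafm1 (−2.58), Rab5if (−2.58), Rab24 (−2.57), Fnta (−2.45) and Kansl2 (−2.24). Within the Pten group, mean CPM per cell in the lettered and the unlettered series was 24.0 and 356 for Habp4, 33.1 and 283 for Pink1, 16.5 and 219 for Rab24, and 21.5 and 130 for Kansl2. All Pten CNTF cells came from an unlettered series. Against the 11 unlettered Pten Socs3 CNTF cells alone the log2 ratio was 0.044 for Kansl2 and −0.68 for Fnta, while Habp4 (−2.04), Rab24 (−2.66) and Pink1 (−3.07) stayed lower with Pten Socs3 CNTF.

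RGC subclass markers also differed in the share of cells. Spp1 was found in 42.7% of Pten cells, 8% of Pten CNTF cells, 15.7% of regenerating Pten Socs3 CNTF cells and 9.09% of surviving cells. Kcng4 was found in 40.2%, 0%, 5.42% and 3.03% of these groups in turn. Trarg1 ran the other way, with 26.5%, 44%, 68.1% and 75.8%, and in CPM it was higher in surviving than in regenerating cells (604 against 202.1). Penk was found in 29.5% of regenerating and 12.1% of surviving Pten Socs3 CNTF cells, and Col25a1 in 35.5% and 69.7%. Tbr1 was found in 16.2% of Pten cells and 4.22% of regenerating Pten Socs3 CNTF cells, and Opn4, the gene of melanopsin, in 17.1% and 14.5%. Foxp2 was found in 17.1% and 39.2%.

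**Figure D4:**
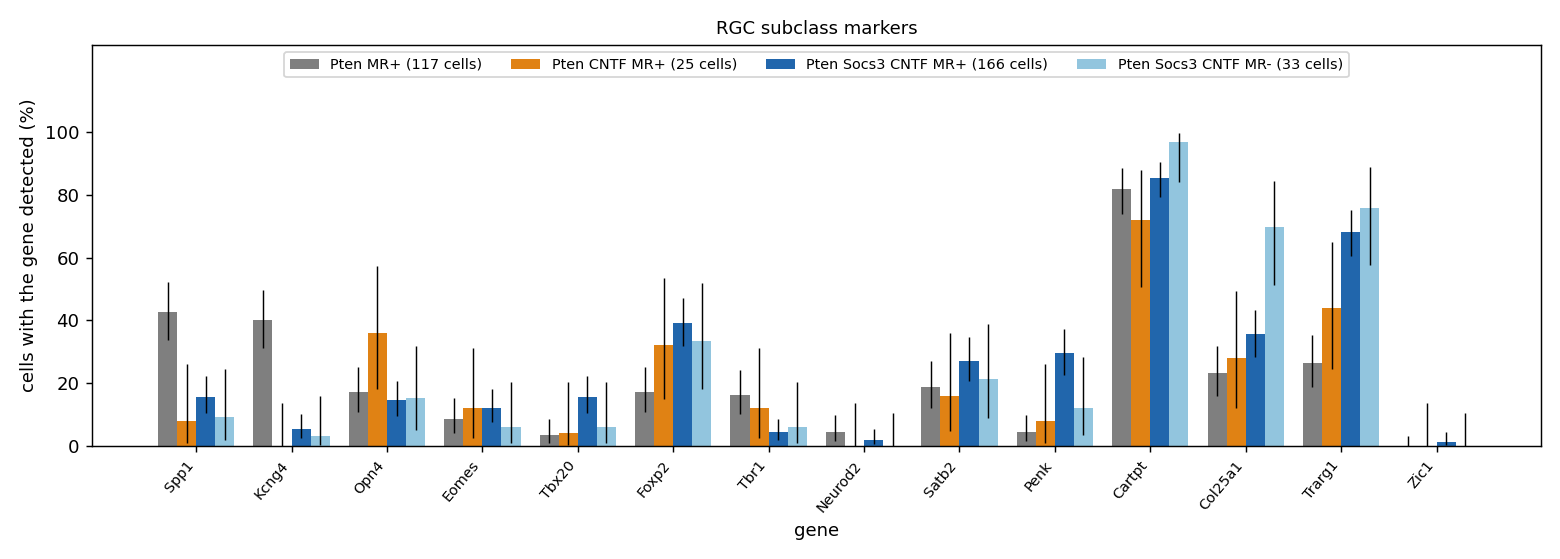
Percent of cells of the 4 groups with each RGC subclass marker after thinning to 100000 reads, with exact 95% intervals. Spp1 and Kcng4 were most frequent in Pten cells (42.7% and 40.2%), and Trarg1 in surviving cells (75.8%).

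Median log2 ratios of subclass marker lists, in the order regenerating over surviving, Pten Socs3 CNTF over Pten, Pten CNTF over Pten and Pten Socs3 CNTF over Pten CNTF, were 1.35, −1.91, −2.67 and 1.43 for alpha markers. With the 2 members at 0 reads in Pten CNTF cells taken against the floor of 3 reads, the last 2 became −4.25 and 3.09. They were 1.78, −0.93, 0.54 and −1.47 for Eomes or photosensitive, −1.25, 0.58, 0.13 and 0.28 for Foxp2, and 0.69, −1.90, −0.87 and −1.72 for Tbr1 markers. Neurod2 markers, of which only Penk and Satb2 were measured, had 2.46, 3.20, 1.79 and 1.41. Direction-selective markers had −0.65, −0.22, 0.40 and 0.51, and Trarg1, the measured Tusc5 marker, −1.57, 1.63, 0.07 and 1.56. Many of these turned between title series. For regenerating over surviving cells Tbr1 markers were −0.40 in D, 1.48 in F, −0.47 in R and −2.75 in the unlettered cells, where alpha (−1.33) and Eomes or photosensitive markers (−1.18) turned as well. For Pten Socs3 CNTF over Pten CNTF, Neurod2 markers were 2.40 in D, 0.49 in F, −0.07 in R and −1.28 in the unlettered cells. In the same order direction-selective markers were 0.87, −0.40, −0.19 and −3.39, and Foxp2 markers −0.64, 0.36, 0.52 and −1.91. For Pten Socs3 CNTF over Pten, direction-selective markers were 0.72 in D and −1.05 in F, and Foxp2 markers −0.15 and 0.85. Against Pten series C and then the unlettered Pten series, Trarg1 was 0.18 and 3.44 for Pten Socs3 CNTF and −1.25 and 2.01 for Pten CNTF. In the same order Eomes or photosensitive markers were 0.34 and −1.24 for Pten Socs3 CNTF, and Tbr1 markers 0.86 and −1.42, Foxp2 markers −0.39 and 0.35 and direction-selective markers −0.16 and 0.33 for Pten CNTF. Pan-RGC markers, on which cells were kept, had −0.09, 0.34, −0.36 and 0.95, and in the unlettered cells −2.17 for the first, −1.51 for the second and −0.90 for the last.

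Markers of other cell types were read in the same order. Microglia or macrophage markers had medians of 2.17, 1.45, −0.74 and 2.60, rod markers −0.56, −0.15, 3.57 and −3.72, and cone markers −0.97, 0.44, 2.98 and −2.60. Microglia or macrophage markers were −1.51, −2.10 and −1.01 in the unlettered Pten Socs3 CNTF cells for the first, second and last comparison. For Pten CNTF over Pten they were −1.20 against series C and 0.61 against the unlettered Pten series. For regenerating over surviving cells rod markers were 0.17 in D and −0.89 in R, and cone markers −1.38 in D and 0.23 in F. Muller glia markers, which include Apoe and Dkk3, had 1.22, 1.21, −0.16 and 0.49, but −0.35, −1.53 and −1.23 in the unlettered cells for the first, second and last. Bipolar markers had 0.67, 0.07, −0.01 and 0.08. Against Pten series C and then the unlettered Pten series, they were 0.85 and 0.05 for the second comparison and 1.60 and −0.10 for the third. The pan-RGC rule had left out cells with amacrine markers, mostly surviving and Pten CNTF cells. In the kept cells amacrine markers, with 3 measured genes, had medians of 1.40, 1.36, −3.41 and 3.28. The first of these was −1.46 in series D and 1.98 in F, and the second −0.95 and 2.28 in those series, −0.21 against Pten series C and 4.11 against the unlettered Pten series. Astrocyte and endothelial markers had only 2 measured genes each. Astrocyte markers had −1.26, −1.73, −1.41 and −0.32, and endothelial markers 0.79, 1.25, 2.23 and −0.98. Only the second astrocyte and the third endothelial median lay outside the random lists. The second endothelial median joined genes of opposite sign, Ly6c1 (3.80) and Flt1 (−1.30). Against Pten series C and then the unlettered Pten series, astrocyte markers were −0.28 and −1.90 for the second comparison. They were −0.004 and −1.62 for the third. No T cell or pericyte marker reached 5 CPM. At least 2 microglia or macrophage markers were present in 36.7% of regenerating Pten Socs3 CNTF cells, against 9.09% of surviving, 6.84% of Pten and 8% of Pten CNTF cells.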

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

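The tests on the single series of surviving cells and on the sex of the animals were chosen only after the result was seen. The tests on Trarg1 cells and on cells without microglia or macrophage markers were added after the data were seen, but what each would show was written down before its own result. The rule for reading every test was tightened after its results were seen.

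Among cells that the pan-RGC rule left out, many carried amacrine markers, which no comparison uses. At least 2 of 6 amacrine markers (Gad1, Gad2, Tfap2a, Tfap2b, Slc6a9, Slc32a1) were present in 42.9% of the left-out Pten CNTF cells (6 of 14, interval 17.7% to 71.1%). They were present in 48.5% of the left-out cells sorted as surviving (16 of 33, 30.8% to 66.5%). Among kept cells the shares were 0% (interval up to 13.7%) and 3.03%. Rod markers were also present in 78.6% of the left-out Pten CNTF cells (11 of 14), against 52% of the kept ones. The left-out cells had median depths of 1032035 and 1527549 reads. They drew attention because a signal stood in data outside the comparisons, above the limit that a count of 0 allows. No explanation was tested. In a clustering of the cells that passed the depth filter, 37 left-out cells formed a cluster of their own led by Nfix, Neurod4, Lgr5, Prox1 and Cplx3. Of these 31 were sorted as surviving and 4 were Pten CNTF cells, while 9 of the 14 left-out Pten CNTF cells fell in a cluster with a median of 3638 genes.

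Regeneration-associated genes were higher in regenerating than in surviving cells, with a median log2 ratio of 1.19. A different share of Trarg1 cells would remove the difference among cells that have Trarg1 at 10 CPM or more. The median there was 1.08, but the subclass mix within those cells was not held constant. RNA from microglia or macrophages would remove the difference in cells without any of their markers, but the median there was 1.17. That source is a hypothesis from its marker list, and the sort for YFP and CD90 would remove such cells though not their RNA. Both values lay outside the range of random lists and above 50% of 1.19, but not by more than the standard deviation between title series (0.674), so these tests keep both explanations open. That spread rests on the 11 unlettered cells, whose median was −0.281. The median by lettered series ran from 0.81 to 1.09 with Trarg1 and from 0.58 to 0.96 without the markers, ranges that were computed after seeing the data. Surviving cells came from 1 series, which stays open as well. Regrowth of the axon, the difference the design names, may account for the pattern but is untested against these.

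Interferon genes were higher in both CNTF groups than in Pten cells, with medians of 3.43 for Pten Socs3 CNTF and 2.94 for Pten CNTF. RNA from microglia or macrophages is argued against: without cells that have any marker of them, the smaller median, that of Pten CNTF over Pten, was 2.67. A different share of Trarg1 cells is argued against by a median of 3.39 among Trarg1 cells in the same comparison. That value rests on 11 Pten CNTF and 28 Pten cells. The subclass mix within those cells was not held constant, so it stays open. The split into lettered and unlettered series is argued against for Pten Socs3 CNTF over Pten, where the smaller median within either kind was 3.44. No title series held cells of both groups, so single series stay open. Sex stays open, since Y-linked transcripts at 10 CPM or more were in 48% of Pten CNTF cells and in 0% of Pten cells. The floxed line (for Pten Socs3 CNTF) and the second virus go with the groups and were not tested. CNTF itself may raise these genes, a hypothesis that cannot be told apart from sex or from single title series here.

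Alpha RGC markers were lower in regenerating Pten Socs3 CNTF cells than in Pten cells, with a median of −1.91. Fewer genes per cell in the unlettered series is one candidate explanation. Within the lettered series, where the median number of genes was 9139 in Pten cells and from 8759 to 9380 in Pten Socs3 CNTF cells, the median was still −1.68. That explanation stays open because −1.68 was not beyond 50% of −1.91 by more than the standard deviation between series, 1.20. In this comparison, however, most unlettered cells were Pten cells (84, against 11 Pten Socs3 CNTF cells), the side with more alpha markers. Against Pten series C alone, with cells weighted equally, the median was −1.62. A loss or a different response of alpha RGCs under the treatments is among the open explanations and was not tested.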

How the results depend on the processing

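The restrictions to cells with Trarg1, to cells without a microglia or macrophage marker and to cells without a rod marker were added as alternatives only after the data were seen. Of the values of the list medians that the design named, 84.2% moved by less than the spread between title series and 15.8% by more. The number counted as reversed was 0. For a list median, a change of sign counted as reversed only where the main median lay outside the random lists. Changes of sign in the JAK-STAT median of Pten Socs3 CNTF over Pten CNTF were therefore not counted. For the other lists 87.6% moved by less, 11.9% by more and 4 values reversed. For single named genes 75.1% moved by less, 24.5% by more and 3 values reversed. Of the shares of cells 79.6% stayed within their intervals and 20.4% moved outside them. Causes were not tested unless given.

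In regenerating over surviving cells, the regeneration-associated median rose from 1.19 to 2.35 with no cell filter and to 2.34 with no pan-RGC rule, both of which add cells with amacrine markers. Without each title series it ran from 1.15 to 1.31. The ion channel median stayed between −0.40 and −0.25 under every alternative run, and without each series between −0.40 and −0.26.

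In Pten Socs3 CNTF over Pten, the JAK-STAT median of 0.95 was 0.25 in unlettered series only, 1.42 in Trarg1 cells, 0.54 without microglia-marker cells and 0.51 without rod-marker cells, and without each series 0.80 to 1.25. The interferon median of 3.43 was 3.01 with a pseudocount of 5 CPM, 3.83 in lettered series only, 4.21 in Trarg1 cells and 2.91 without rod-marker cells, and without each series 3.19 to 3.90.

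In Pten CNTF over Pten, the JAK-STAT median of 1.21 was 1.05 with cells weighted equally, 1.00 with a pseudocount of 5 CPM, 0.99 with no minimum on list members and 1.43 in Trarg1 cells, and without each series 1.27 to 1.51. The interferon median of 2.94 ran from 2.77 to 3.74 without each series.

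In Pten Socs3 CNTF over Pten CNTF, the JAK-STAT median of −0.14 was −0.83 in unlettered series only. It was 0.62 without rod-marker cells, which left 7 Pten CNTF cells, and without each series −0.17 to 0.08. The interferon median of 0.26 was 0.61 both with no pan-RGC rule and in unlettered series only, 0.63 in Trarg1 cells and 0.58 without microglia-marker cells, and without each series 0.20 to 0.28.

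Of the list medians outside the random lists, the ribosomal one reversed in regenerating over surviving cells without series D (−0.085). The growth cone median in Pten CNTF over Pten reversed with no cell filter (−0.020) and without the unlettered Pten series (−0.00744). It was 0.53 without the lettered one. The ion channel median in Pten Socs3 CNTF over Pten CNTF reversed in unlettered series only (−1.26). The JAK-STAT median of that comparison also changed sign, but lay inside the random lists and was not counted. Single genes that reversed were Snca in regenerating over surviving cells with no cell filter (0.14) and no pan-RGC rule (0.013), and Kansl2 in Pten Socs3 CNTF over Pten CNTF in unlettered series only (0.044). The cause was not tested.

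No paired analysis was possible because no label links a cell of 1 group to a cell of another. Regroupings of samples do not apply, since nothing was tested. The 25 Pten CNTF and 33 surviving cells limit shares most, and lettered series give no value where 1 group has none.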

Other observations

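The 7 clusters of cells, described only by their leading genes, included a cluster led by Rsad2, Glis3 and Penk, 76 cells led by Chrna3, Bnc2 and Trarg1, and 56 led by Spp1, Etv1 and Kcng4. Others were 31 cells led by Tbx20 and Prph, 26 led by Jam2, Mmp12 and Tbr1, and 64 cells with a median of 3638 genes. The groups were spread unequally over the clusters. The Rsad2 cluster held 90 regenerating Pten Socs3 CNTF cells and 5 surviving cells, and the Trarg1 cluster 28 and 22. The Spp1 cluster held 50 Pten cells. Xist is listed at 0 in all groups. Y-linked transcripts at 10 CPM or more were present in 69.7% of surviving cells (51.3% to 84.4%).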
